A study of Mus musculus with 8 samples.

How the data were processed

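Total RNA from 8 samples of mouse embryonic stem cells was labelled with Cy3 and hybridised to 1 array each, per the labels. The cells grew on gelatin in medium with serum and LIF, and their genotype is such that OHT leaves them without RAS. Groups, replicate numbers and cell pools came from the sample titles and source names: 4 groups of 2 arrays, each sample a mix of 2 clones, with OHT given for at least 2 days. Slide 1 held 6 arrays and slide 2 held replicate 2 of both wild type groups, and each slide was scanned in a single session, so slide and scan are 1 batch variable.

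The deposited scanner files hold spot intensity values made with Agilent Feature Extraction 11.5.1.1, per the file headers: background-subtracted, detrended within the array and not scaled between arrays. Deposited median pixel intensity of each spot and of its local background entered the background correction by normexp. Other columns used, per the file headers, are 0 or 1 flags for spots well above background, saturated or non-uniform. A deposited value table of the series holds log2 values relative to a typical level of each probe, as far as the values show, with column medians from -0.158 to 0.133. Of its 55407 entries 99.3% matched the log2 pattern of some scanner spot within 0.05, but 1 did so under its own probe name, and by name the correlations with the scanner values ran from -0.0087 to 0.0027. That table was therefore not used to name or test anything, and its scaling between arrays and its naming stay unknown. How the authors normalised or tested the arrays is not given in the sources used here.

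Each array had 62976 spots, of which 59305 were no controls, for 55681 distinct probes. Control spots and spots with a non-uniformity or population outlier flag were left out, spots of a probe were averaged, and the log2 of the processed signal minus each array's 75th percentile was tested. Probe accessions were named through a RefSeq gene table of assembly GRCm38.p6, used for names only: 28026 probes matched 21154 genes and 27655 stayed unnamed. A probe was tested if it was well above background on both arrays of at least 1 group. Of several probes of a gene, as 3972 genes had, the one with the highest mean over all arrays was kept, which left 15180 genes. Nras had 3 probes, all well above background on 8 arrays and with changes of the same sign in both genotypes, and Hras had 2, of which the second was well above background on 1 array. Where a gene was below background on both arrays of a group, its fold is a bound, taken against the higher of the dimmest probe well above background and its own signal on each array of the dim group.

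Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on 4 group means, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. With 2 arrays a group this fit has 4 residual degrees of freedom and treats the arrays of a pool as independent, though the same pool was sampled with and without OHT. The 5 comparisons were OHT against untreated in each genotype, the difference of those effects, and the labelled knockout against the wild type without and with OHT. Gene lists, 24 in all, were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and with fry as alternatives. Some genes stand in several lists: the formative list shares 6 genes with TGF-beta, BMP and Nodal, 3 with DNA methylation, 2 with WNT and 2 (Krt8 and Krt18) with trophoblast, and RAS/ERK targets share 3 with the ETS family. Their tests are therefore not independent. Fry asks whether the members of a list move one way on balance and does not set them against other genes. All tests were two-sided. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

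The tests, gene lists, comparisons and a first set of alternatives were set before the data were examined. For each comparison the genes to be named were Erf and the RAS genes whatever their values, the largest changes among genes that passed, up to 4 passing members of each list or else the member with the smallest p, and, where no gene passed, the 4 genes with the smallest p in each direction. Some of the genes this rule names are not reported here. For the difference of the effects and the comparisons of genotypes, list members are named from the lists that passed, besides Elf3 and Oas1a. Members that passed over a list alone and genes of the paired fit are named besides, and were chosen after their values were seen.

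Pairing follows from the source names, since the same pool was sampled with and without OHT within a genotype. Deviations of replicates from their group means correlated across genes at 0.658 between the wild type groups and 0.443 between the labelled knockout groups, or 0.738 and 0.705 with dark patches left out, against 0.226 to 0.508 (0.406 to 0.550) across genotypes, where only the pool letter is shared. The median residual SD fell from 0.305 with group means to 0.111 with pools as blocks, which leave 2 residual degrees of freedom.

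Dark patches were found after the values were seen. A spot was put in one when the median deviation of the 12 spots nearest to it from the probes' medians over arrays was under -1 on the log2 scale. The patches held 1797 spots of replicate 1 and 846 of replicate 2 of the labelled knockout after OHT, 488 of untreated wild type replicate 1, and 0 to 146 of the others, and 0 on any array once positions were shuffled. The paired fit, which joins the pool block, the removal of dark patches and a trended and robust eBayes, was added at that point, as were its versions without single pools and with a limit of -0.5. Its list tests used the pool block and the removal of dark patches but not the trended and robust variance.

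The alternatives set beforehand covered quantile normalisation, median centring, normexp with an offset of 50 and quantile normalisation, no filter and a stricter filter on dim probes, a floor, other ways to join probes, trended variance, array weights, blocks for replicate and slide, slide 1 alone, fits of the compared groups alone, other thresholds, and the omission of each array in turn. The fits were tested on simulated data of 14227 genes for OHT in the wild type. There the fit on group means recovered 4% of genes changed 2-fold and 39% of those changed 4-fold, pools as blocks recovered 43 and 69%, and with a trended and robust variance 47 and 71%. Camera, at an unadjusted p under 0.05, found 40 of 40 simulated lists lowered by 0.5 and called 1 of 40 unchanged ones. The simulated genes varied independently of one another, so this does not show how camera behaves where list members are correlated. The simulated spread was taken from values with dark patches left out, so the recovery rates do not cover fits that keep the patches.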

Results

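Gene expression was measured on 8 one-colour microarrays of mouse embryonic stem cells engineered so that 4-hydroxytamoxifen (OHT) leaves them without RAS. The cells were labelled ERF wild type or ERF knockout, and each genotype was left untreated or given OHT for at least 2 days, which made 4 groups of 2 arrays. ERF is a transcriptional repressor of the ETS family that the kinase ERK keeps out of the nucleus, so the design asks how much of the response to losing RAS runs through it. Per the labels, each sample was a mix of clones, and the source names define 4 cell pools: A1 and B1 of the wild type and A2 and B2 of the labelled knockout. Replicate 1 of each group came from an A pool and replicate 2 from a B pool, and the same pool was sampled with and without OHT. The labels call the replicates of a group biological replicates, so p-values on the group means measure the spread between pools of clones. Those tests do not use the pairing of the pools. With pools as blocks, p-values measure how far the change after OHT varies between pools. Between 54.0 and 63.6% of the spots on an array were well above background, and 0 spots were saturated. The number of arrays limits the precision of every value.

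Erf itself, measured on all 8 arrays, separated the pools more than the genotypes. Relative to each array's 75th percentile on the log2 scale, the wild type read 5.12 and 5.43 untreated and 4.98 and 4.93 after OHT. Pool A2 of the labelled knockout read 3.45 untreated and 3.92 after OHT, while pool B2 read 5.65 and 5.31, at the wild type level. Where the Erf probe lies relative to the deletion is not given in the sources used here, so these levels check the labels in neither direction, and the term labelled knockout is used throughout. The probes of Hras and Nras, deleted in all pools per the labels, read 2.78 to 3.21 and 0.87 to 2.09, and their places relative to the deletions are likewise unknown. With limma on the group means, none of Erf, Hras and Nras passed in any of the 5 comparisons, with adjusted p from 0.999 to 1.00. In the paired fit, which is described further on, Hras fell by 0.28 in the wild type (limma adjusted p 0.0395) and Nras was 0.38 higher after OHT in the labelled knockout (adjusted p 0.0337).

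The first comparison asks what OHT, which leaves the cells without RAS, did to cells that keep ERF. No group given OHT keeps RAS, so effects of OHT itself cannot be told apart from those of losing RAS. Genes that report ERK activity were lower in the wild type after OHT: 29 of the 33 measured RAS/ERK target genes were below their untreated level, 24 of them in both pairs, with a median log2 change of -0.51. Spry4 and Spry2, which encode feedback inhibitors of receptor tyrosine kinase signalling, changed by -2.98 and -1.77. Dusp6 and Dusp4, phosphatases that switch ERK-family kinases off, changed by -2.32 and -2.40, and the immediate early gene Egr1 by -2.39. Adjusted over the list alone, 8 members passed with limma: these 5, Etv1 (-1.62), the proliferation factor Myc (-2.38) and the RAS inhibitor Spred1 (-1.59). The list passed camera with an adjusted p of 1.04e-09. It had an adjusted p of 0.574 with an estimated correlation, the highest over its alternatives, which went down to 2.71e-10. Within slide 1 its median was -0.57 (adjusted p 1.08e-09), within slide 2 it was -0.56, and with the slide as a block the adjusted p was 9.12e-08.

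Genes of the formative and primed epiblast, the state that follows naive pluripotency, went the same way in the wild type. Of 28 measured members 22 were lower, with a median of -0.59. Lef1, a WNT effector, changed by -2.85 ± 0.23 (SE, 2 arrays a group), and Otx2, a transcription factor that starts the exit from naive pluripotency, by -2.15. The transcription factor genes Tcf15 and Foxd3 changed by -1.69 and -1.14, the de novo methyltransferase gene Dnmt3b by -1.25 and its partner Dnmt3l by -0.67. The Nodal co-receptor gene Tdgf1 was lower as well, whereas the Nodal antagonist genes Lefty1 and Lefty2 were 1.15 and 1.42 higher. These 9 genes and Myc passed limma adjusted over the list alone. Camera gave the list an adjusted p of 1.98e-04, or 0.574 with an estimated correlation, and 6.21e-04 with the slide as a block. Its median was -0.73 within slide 1 (adjusted p 9.36e-05) and -0.61 within slide 2. Core pluripotency genes were lower too, with 14 of 17 below their untreated level and a median of -0.33, and Utf1, a chromatin protein gene of stem cells, changed by -1.52 and passed adjusted over the list alone. That list had an adjusted p of 0.00195, or 0.574 with an estimated correlation, 0.00137 with the slide as a block and 0.0207 within slide 1. Its median was -0.32 within slide 1 and -0.38 within slide 2.

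Trophoblast genes, which mark the lineage of the placenta, were higher in the wild type after OHT. They were higher in 15 of 20 cases, with a median of 0.52, and Gata2 (2.53) and Tfap2c (1.41), both trophoblast transcription factor genes, passed adjusted over the list alone. The list had an adjusted p of 0.00680, or 0.574 with an estimated correlation, 0.0102 with the slide as a block and 0.0930 without replicate 1 of the OHT group. Its median was 0.51 within slide 1 (adjusted p 0.00588) and 0.57 within slide 2.

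Another 4 lists passed more narrowly in the wild type. TGF-beta, BMP and Nodal response genes had a median of 0.35 (adjusted p 0.0439) with Id4, an inhibitor of DNA binding, 1.47 higher and passing over the list alone, as did Lefty2. Cholesterol synthesis genes had a median of 0.16 (adjusted p 0.0415), WNT response genes one of -0.40 (adjusted p 0.0439) and DNA methylation machinery one of -0.22 (adjusted p 0.0439), with Lef1 and Dnmt3b passing over their lists alone. With an estimated correlation the adjusted p values were 0.574 for TGF-beta, BMP and Nodal, 0.793 for cholesterol synthesis, 0.574 for WNT and 0.640 for DNA methylation. Blocking by pool gave 0.0698, 0.0711, 0.0911 and 0.0698 in that order. The slide block gave 0.0656, 0.0266, 0.0464 and 0.0464, and slide 1 alone had medians of 0.37, 0.07, -0.38 and -0.16 with adjusted p values of 0.108, 0.0207, 0.165 and 0.260, against slide 2 medians of 0.28, 0.22, -0.38 and -0.29. Leaving out single arrays, which unbalances the pools on the group means, ended each of these calls. Without replicate 2 of the untreated group the adjusted p was 0.252 for TGF-beta, BMP and Nodal and 0.443 for DNA methylation, and without replicate 1 of the OHT group it was 0.223 and 0.176. Without replicate 1 of the untreated group it was 0.702 for cholesterol synthesis and 0.253 for WNT, and without replicate 2 of the OHT group it was 0.632 and 0.425.

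Over all 15180 genes tested in the wild type, limma on the group means called 0 after OHT, with 905 at an unadjusted p under 0.05 (391 higher and 514 lower) where chance gives 759. The smallest adjusted p values, 0.0872 to 0.118, belonged to Lrrc15 (2.64 ± 0.20), the lipid droplet gene Cidea (1.91 ± 0.17), the tubulin modifier gene Ttll6 (1.87 ± 0.17) and the autophagy receptor gene Calcoco2 (3.03 ± 0.31) among higher genes. Among lower ones they belonged to Dusp6 (-2.32 ± 0.17), the phosphodiesterase gene Pde2a (-2.22 ± 0.18), Lef1 and the sialyltransferase gene St6gal2 (-2.19 ± 0.21, or -0.73 with normexp), with SE over 2 arrays a group. Other settings of limma called 5 genes with normexp background correction, 4 over probes well above background on all 8 arrays, 14 with array weights and 3 with a trended and robust variance. The pool block alone called 0. Leaving out replicate 2 of the untreated group gave 29 calls, of which 89.7% had their spot in a dark patch (an area of low signal on the chip) of the array that remained.

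More calls came from a fit that was chosen after the values were seen and changed 3 choices at once. This paired fit took the 4 pools as blocks, left out spots in dark patches and used a trended and robust variance; in the wild type the pool block called 1458 genes with that variance alone and 267 with dark patches out alone. It called 2686 genes after OHT in the wild type, 1183 higher and 1503 lower, of which 485 changed at least 2-fold, and 2149 of 15167 in the labelled knockout, 694 higher and 1455 lower, 200 of them at least 2-fold. In the wild type it called 17 RAS/ERK targets lower, and only Jun and Emp1 of that list higher. It called 10 naive pluripotency genes higher and 5 lower, from a list that did not pass camera there on the group means (adjusted p 0.206). In the paired fit Nanog rose by 1.35, Prdm14, a repressor of differentiation genes, by 2.12, Tbx3 by 1.88, Tfcp2l1 by 1.39 and Klf2 by 0.86, while Gbx2 fell by 2.54. The same fit in the labelled knockout gave 1.09 for Nanog, 1.67 for Prdm14, 1.96 for Tbx3, 1.11 for Tfcp2l1, 0.81 for Klf2 and -2.16 for Gbx2, each passing. With one pool left out the wild type counts ran from 465 without B1 to 3164 without A2, with 575 without A1, and the labelled knockout counts from 667 without A2 to 1087 without B1, with 903 without B2 and 1060 without A1.

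**Figure D1:**
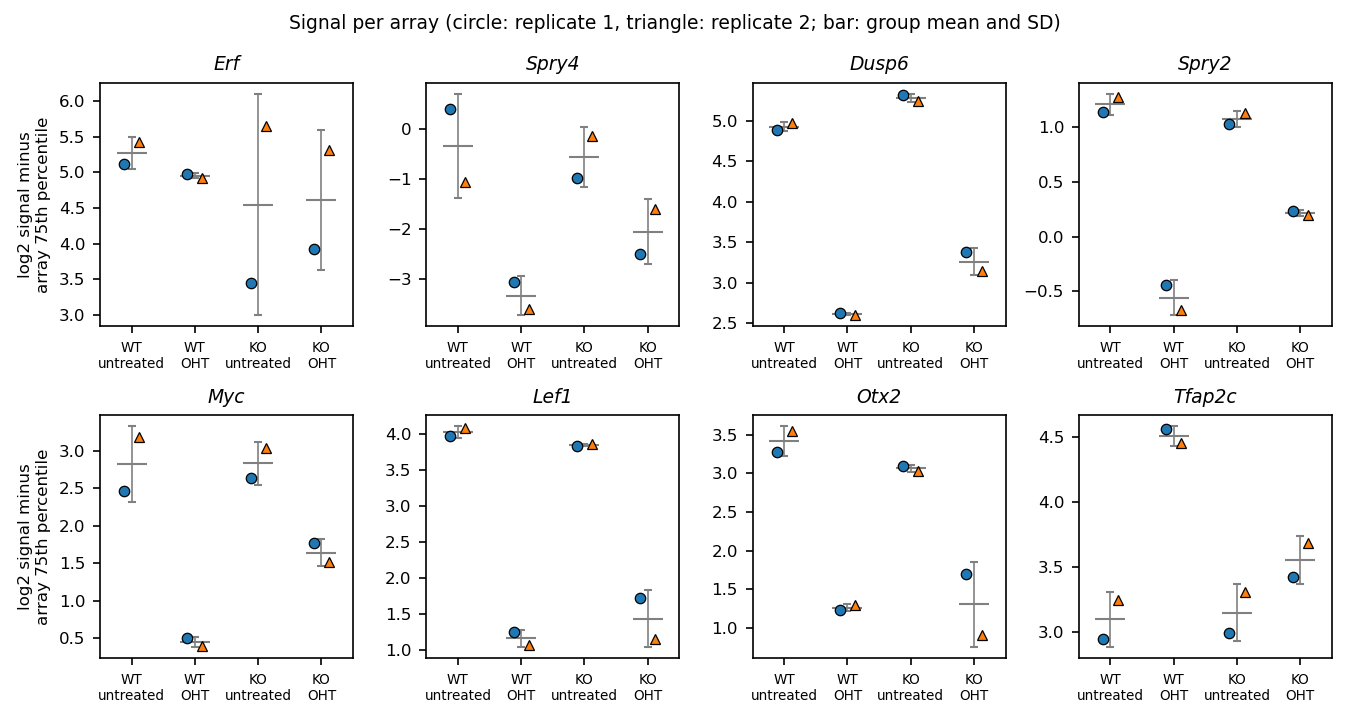
Log2 signal minus the array's 75th percentile (vertical axes) for 8 genes in the 4 groups, with one symbol per array and bars for the mean and SD of 2 arrays. Spry4, Dusp6, Spry2, Myc, Lef1 and Otx2 lie lower after OHT in every pair, Tfap2c lies higher, and Erf in pool A2 (3.45 and 3.92) lies below the other arrays.

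The second comparison asks the same of cells labelled as lacking ERF. RAS/ERK target genes were again lower, in 24 of 33 cases and in 23 of them in both pairs, with a median of -0.33. Dusp4 and Dusp6 changed by -2.02 each, Etv1 by -1.59, Myc by -1.19 and Spry2 by -0.86, and these 5 passed limma adjusted over the list alone. The list had an adjusted p of 7.83e-07, or 0.511 with an estimated correlation, over alternatives that went down to 3.10e-10, and 0.273 without replicate 2 of the OHT group. All 4 arrays of this comparison lay on slide 1, and with the slide as a block the adjusted p was 2.73e-06.

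Formative and primed epiblast genes had a median of -0.55 in the labelled knockout, with 20 of 28 lower. Lef1 (-2.40), Otx2 (-1.76), Tcf15 (-1.36), Dnmt3b (-0.87) and Myc passed over the list alone on the lower side, and Lefty1 (1.14) and Lefty2 (1.24) on the higher side. Over settings other than the omission of single arrays, Dnmt3b ran from -2.03 to -0.76. The adjusted p was 4.39e-06, or 0.511 with an estimated correlation, and 0.0965 without replicate 1 of the untreated group. Core pluripotency genes (median -0.25, adjusted p 0.00295) and DNA methylation machinery (median -0.17, adjusted p 0.0180) were lower, while fibroblast genes (median 0.53, adjusted p 0.00295), cholesterol synthesis genes (median 0.29, adjusted p 0.00834) and TGF-beta, BMP and Nodal response genes (median 0.43, adjusted p 0.0132) were higher. With an estimated correlation the adjusted p values of these 5 lists were 0.517, 0.517, 0.593, 0.593 and 0.517. Prrx1, a mesenchymal transcription factor gene, led the fibroblast genes at 1.06 ± 0.38 (0.67 to 1.45 with 1 array left out, 0.60 with normexp), and 20 of 21 members were higher, but none passed over the list alone.

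Those 5 calls were each lost when certain single arrays of the labelled knockout were left out, which unbalances the pools on the group means. Without replicate 1 of the OHT group the adjusted p values were 0.232 for core pluripotency, 0.232 for DNA methylation, 0.762 for fibroblast genes with the direction turned, 0.568 for cholesterol synthesis and 0.595 for TGF-beta, BMP and Nodal. Without replicate 2 of the untreated group they were 0.279, 0.330 and 0.662 for the first 3 and 0.594 for TGF-beta, BMP and Nodal. Cholesterol synthesis had 0.221 without replicate 1 of the untreated group, and DNA methylation had 0.0728 without replicate 2 of the OHT group.

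Across all 15180 genes of the labelled knockout, limma on the group means called 0, with 585 at an unadjusted p under 0.05 (377 higher and 208 lower). Chance gives 759. The smallest adjusted p values (0.189 to 0.242) among higher genes were those of the transporter gene Slc16a12 (at least 3.28-fold), Ttll6 (1.54), Pabpn1l (at least 3.06-fold) and the homeobox gene Dmbx1 (2.00, or 1.22 with normexp). Among lower genes they were those of Zp3r (at least 1.26-fold), Dusp6 (-2.02 ± 0.17), Pde2a (-2.03 ± 0.18) and Lef1 (-2.40 ± 0.23). The pool block alone called 0, and with a trended and robust variance it called 383. Leaving out replicate 2 of the OHT group gave 384 calls, leaving out replicate 1 of it gave 135, and leaving out replicates 1 and 2 of the untreated group gave 6 and 3. Of the 384, 90.1% had their spot in a dark patch of the remaining OHT array, and of the 135, 90.4% did.

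**Figure D2:**
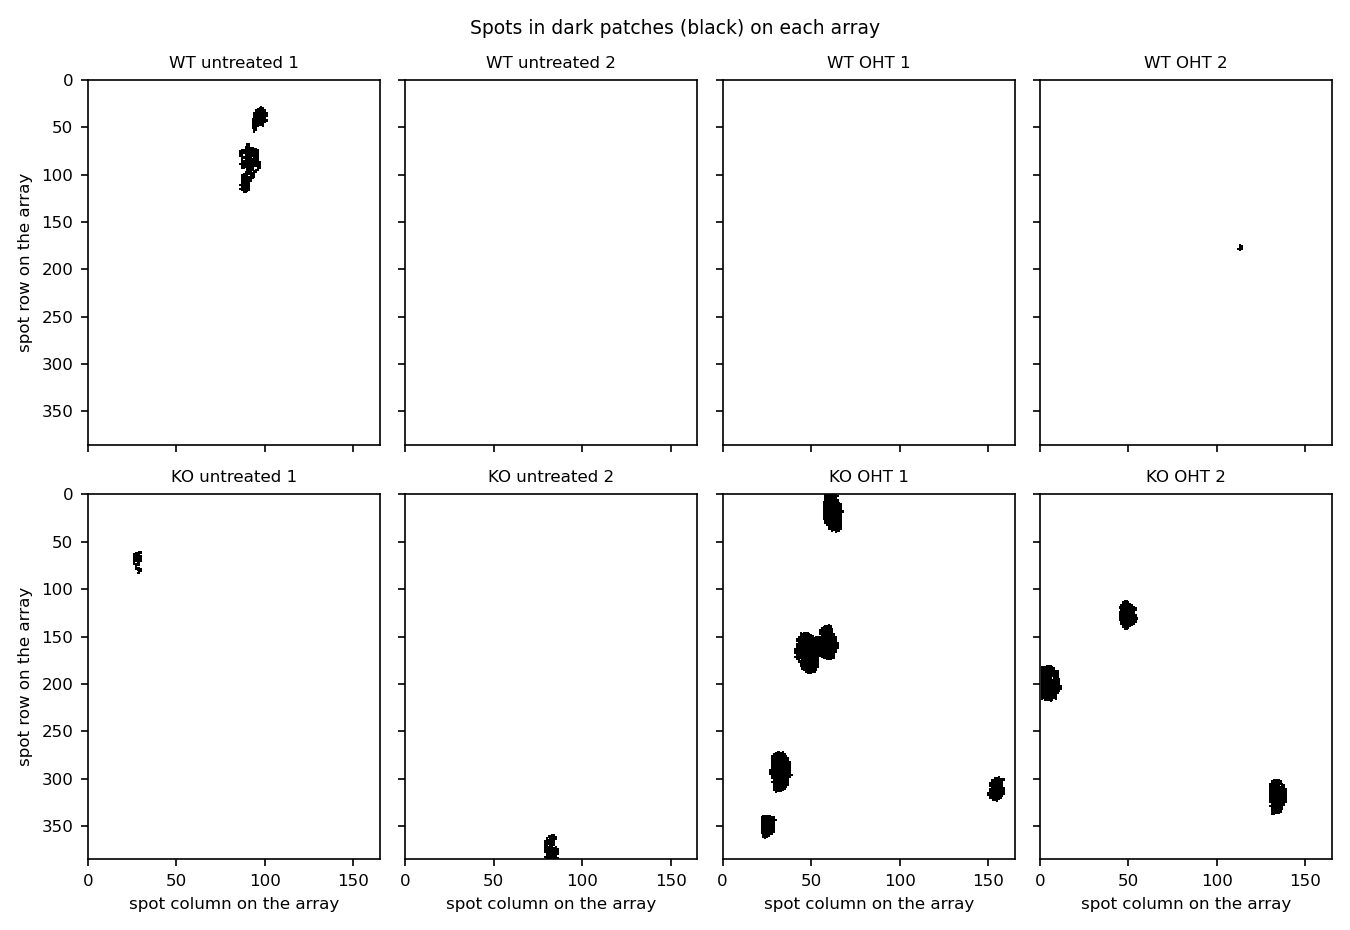
Positions on the array (row against column) of the spots in dark patches, black, for each of the 8 arrays. Replicate 1 of the labelled knockout after OHT had 1797 such spots and replicate 2 had 846, while replicate 2 of the untreated wild type and replicate 1 of the wild type after OHT had 0.

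**Figure D3:**
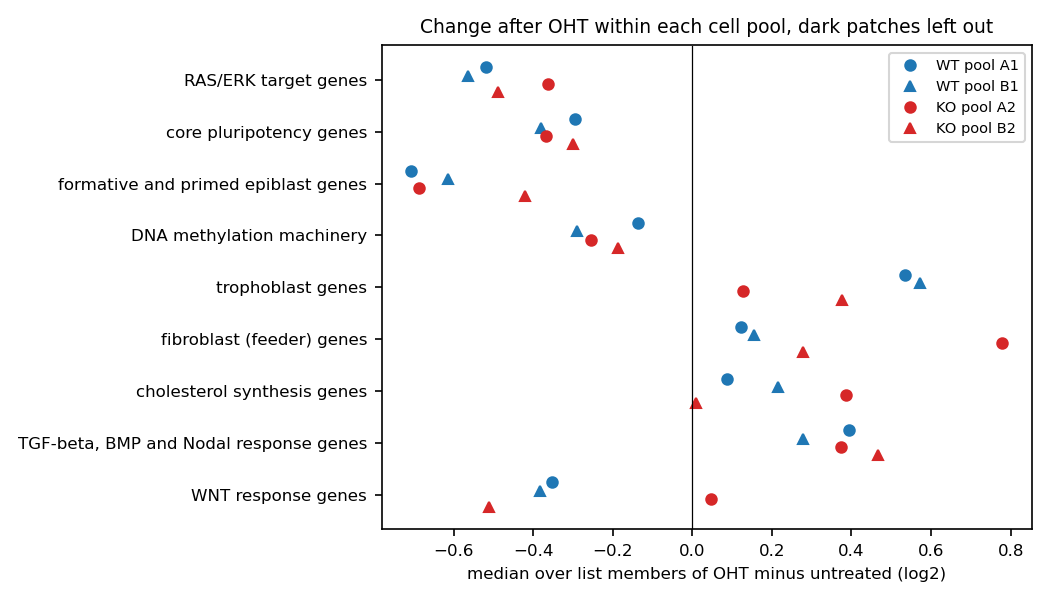
Median log2 change after OHT over the members of each list that passed in either genotype (horizontal axis), one symbol per cell pool, with spots in dark patches left out. RAS/ERK target genes lie at -0.52 and -0.56 in the wild type pools and at -0.36 and -0.49 in the labelled knockout pools, and fibroblast genes reach 0.78 in pool A2.

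Both genotypes shared much of the response. In the paired fit 467 genes rose in both, where independent lists of those sizes would share 54.1, and 831 fell in both, where they would share 144. Both tests use the same estimate of a gene's spread, so the lists are not independent and the excess may be overstated. Genes called in opposite directions numbered 0 among those higher and 3 among those lower in the wild type. Among the largest shared rises were the autophagy receptor gene Calcoco2 (3.04 in the wild type and 2.04 in the labelled knockout), the water channel gene Aqp3 (2.79 and 1.67), the homeobox gene Hesx1 (2.82 and 1.33) and Xaf1 (2.10 and 1.79). Among the largest shared falls were Gbx2, the collagen gene Col6a5 (-2.69 and -1.95), Spry4 (-2.97 and -1.55) and the ETS activator gene Etv4 (-2.09 and -1.90). Across genes, which are not independent replicates, the change in the wild type and that in the labelled knockout correlated with Pearson's r of 0.319 and Spearman's rho of 0.544, or 0.551 and 0.582 with dark patches left out. For 974 genes that moved at least 2-fold in wild type pool A1, by a median of 1.34 (log2), the median change in the same direction was 0.95 in the other wild type pool. It was 0.58 in the mean of the 2 labelled knockout pairs (0.66 in A2 and 0.50 in B2), with the same sign in 87.2 and 78.4%. Chosen on pool B1 instead, where the median was 1.34 too, 915 genes had 0.98 and 0.65 (0.59 in A2 and 0.75 in B2), with the same sign in 90.4 and 83.7%. With dark patches left out the same-sign shares were 89.1 and 82.4% on A1 and 90.6 and 85.4% on B1. Without a filter on dim probes the medians were 0.333 and 0.0812 for genes chosen on A1, and 0.661 and 0.273 on B1. These kept changes carry no test, with 1 pair each way.

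The third comparison, whether the response to OHT differed between the genotypes, bears most directly on ERF. RAS/ERK target genes fell less in the labelled knockout, by a median of 0.30 with 24 of 33 members above 0, and the rise of trophoblast genes was smaller there, by a median of -0.33 with 15 of 20 members below 0. Among their members Myc differed by 1.18 and Spry2 by 0.90 ± 0.24 on one side, and Gata2 by -1.86 and Tfap2c by -1.08 in the paired fit (adjusted p 0.0857) on the other, and none of either list passed over its list alone. Both lists had an adjusted p of 0.0347, or 0.968 with an estimated correlation, over alternatives from 2.75e-04 to 0.991 for RAS/ERK targets and from 3.09e-06 to 0.991 for trophoblast genes. With the slide as a block both had 0.0983. Within slide 1 the medians were 0.25 and -0.17, both with an adjusted p of 0.0819. Blocking by pool gave 0.0913 for RAS/ERK target genes, and leaving out dark patches gave 0.102 for trophoblast genes. In the paired fit they had 0.0384 and 0.0337. That fit without pool A2 gave 0.598 for RAS/ERK targets and 0.143 for trophoblast genes, without A1 it gave 0.0599 and 0.0522, and without B1 it gave 0.0547 for RAS/ERK targets.

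Both list differences were lost when certain single arrays were left out. On the group means this unbalances the pools, so level differences between pools enter the changes. Without replicate 1 of the labelled knockout after OHT the RAS/ERK targets had an adjusted p of 0.801 with the direction turned, and without replicate 1 of the untreated labelled knockout the trophoblast genes had 0.990, also turned. RAS/ERK targets had 0.113 and 0.185 without replicates 1 and 2 of the untreated wild type, 0.284 without replicate 1 of the wild type after OHT and 0.536 without replicate 2 of the untreated labelled knockout. Trophoblast genes had 0.269 without replicate 2 of the untreated wild type, 0.344 without replicate 1 of the wild type after OHT and 0.644 without replicate 2 of the labelled knockout after OHT.

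For single genes the difference of the effects gave no call. Limma on the group means called 0 of 15180, with 196 at an unadjusted p under 0.05 (166 higher and 30 lower) where chance gives 759. The paired fit called 0 of 15167, with a lowest adjusted p of 0.0857. It had 1336 genes at an unadjusted p under 0.05, more than the 759 that chance gives over 15180 genes, whereas the group means gave fewer. The smallest p values on the higher side were those of Pabpn1l, the platelet glycoprotein gene Gp1bb, Slc16a12 and Kctd7, with adjusted p from 0.924 to 1.00. On the lower side they were those of Zp3r, Cidea (-1.31 ± 0.24), Slfn1 and the aldehyde dehydrogenase gene Aldh3b2. All but Cidea were below background on both arrays of 1 or 3 groups, so their size is not measured. With a floor under dim probes the differences were 2.02 for Pabpn1l, 0.99 for Gp1bb, 1.74 for Slc16a12, 2.00 for Kctd7, 0.08 for Zp3r, -0.48 for Slfn1 and -0.13 for Aldh3b2. Leaving out replicate 2 or replicate 1 of the labelled knockout after OHT gave 325 and 122 calls, replicate 2 of the untreated wild type 15 and replicate 1 of the untreated labelled knockout 3. The paired fit without pool B2 called 65, and without A1, A2 and B1 it called 3, 10 and 10.

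The fourth comparison sets the untreated labelled knockout against the untreated wild type. Naive pluripotency genes were lower in the labelled knockout, in 28 of 30 cases with a median of -0.31, and primitive endoderm genes, which mark the yolk sac lineage, had a median of -0.33. Trophoblast genes had a median of 0.58 and target genes of the tumour suppressor p53 one of 0.34. Members with the smallest p were Spic (-1.54) for naive pluripotency, the hepatocyte factor gene Hnf4a (-1.62) for primitive endoderm, Gata2 (0.74) for trophoblast and the apoptosis gene Bax (0.28) for p53, none passing over its list alone. With 1 array left out Spic ran from -2.74 to -0.35, Hnf4a from -2.14 to -1.10 and Gata2 from 0.38 to 1.11, and normexp gave -0.25 for Spic, -0.55 for Hnf4a and 0.15 for Bax, of which Spic and Hnf4a were below background on 1 array of a group. By pool the untreated medians between A2 and A1 and between B2 and B1, which lie on different slides, were -0.58 and 0.06 for naive pluripotency, -0.06 and -0.79 for primitive endoderm, 1.06 and 0.14 for trophoblast and 0.58 and 0.08 for p53 targets. The adjusted p values were 0.0123, 0.00675, 0.00675 and 0.0123 in that order, or 0.950, 0.881, 0.881 and 0.950 with an estimated correlation. With the slide as a block they were 0.158, 0.192, 0.139 and 0.329, and within slide 1 the medians were -0.12, -0.24, 0.24 and 0.19 with adjusted p values of 0.330, 0.327, 0.0867 and 0.228. Without replicate 2 of the untreated wild type they were 0.295, 0.378, 0.0953 and 0.245. Without replicate 1 of the untreated labelled knockout they were 0.463 for naive pluripotency and 0.897 for trophoblast, both turned in direction, and 0.977 for p53 targets, and without replicate 2 of it 0.277 for primitive endoderm.

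Among single genes of the untreated groups, limma called 0 of 15180, with 206 at an unadjusted p under 0.05 (38 higher and 168 lower) where chance gives 759. The lowest adjusted p was 1.00, and there were 0 calls under each of 18 other settings that kept all arrays. The smallest p values belonged to Slfn1 (at least 1.51-fold higher in the labelled knockout), the meiosis gene Spata22 (at least 1.55-fold higher), Trim34a (0.72, or 0.44 with normexp) and the phosphatase gene Ptprd, which was below background in the wild type. On the lower side they belonged to the innate immunity kinase gene Irak4 (at least 1.69-fold lower), Cd7 (at least 2.67-fold), Slc16a12 (at least 1.60-fold) and the claudin gene Cldn23 (-0.995, or -0.29 with normexp). Leaving out replicate 2 of the untreated wild type gave 21 calls, and leaving out replicates 1 and 2 of the untreated labelled knockout gave 6 and 2.

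The fifth comparison, between the genotypes after OHT, showed RAS/ERK target genes higher in the labelled knockout, in 27 of 33 cases with a median of 0.64. By pool the median was 0.85 between A2 and A1, with 28 of 33 higher, and 0.06 between B2 and B1, which lie on different slides, with 19 of 33 higher. Spry4 stood 1.27 higher, Myc 1.19, Fos 1.13 and Spry2 0.77. Fibroblast genes were higher as well (median 0.53), led by the collagen gene Col5a2 (1.22, or 0.56 to 1.87 with 1 array left out and 0.33 with normexp), with medians of 1.29 between A2 and A1 and -0.30 between B2 and B1, while primitive endoderm genes (median -0.30, Hnf4a -1.34, or -2.05 to -0.63 with 1 array left out and -0.45 with normexp) and naive pluripotency genes (median -0.21) were lower. Pecam1, the naive list's member with the smallest p (-1.52, or -2.23 to -0.81 with 1 array left out and -0.84 with normexp), had a spot in a dark patch. The medians between A2 and A1 and between B2 and B1 were -0.04 and -0.76 for primitive endoderm and -0.53 and -0.05 for naive pluripotency. The adjusted p values were 3.56e-05 for RAS/ERK targets, 0.0242 for fibroblast genes, 0.00811 for primitive endoderm and 0.0403 for naive pluripotency, and each was 0.957 with an estimated correlation. With the slide as a block they were 9.29e-04, 0.00113, 0.150 and 0.107, and within slide 1 the medians were 0.64, 0.79, -0.12 and -0.20 with adjusted p values of 1.54e-04, 0.00111, 0.132 and 0.0270. Blocking by replicate gave 0.101 for naive pluripotency. Without replicate 1 of the labelled knockout after OHT the adjusted p was 0.430 for RAS/ERK targets, 0.542 with the direction turned for fibroblast genes and 0.623 for naive pluripotency. Without replicate 1 of the wild type after OHT it was 0.420 for both fibroblast and naive pluripotency genes, without replicate 2 of it 0.150 for primitive endoderm, and without replicate 2 of the labelled knockout after OHT 0.549 for primitive endoderm and 0.0804 for naive pluripotency. Naive pluripotency had 0.0533 and 0.0535 without replicates 1 and 2 of the untreated wild type.

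For single genes after OHT, limma called 0 of 15180 between the genotypes, with 334 at an unadjusted p under 0.05 (212 higher and 122 lower) where chance gives 759. There were 0 calls under each of 18 other settings that kept all arrays. The smallest adjusted p values (0.754) belonged to Pabpn1l (at least 3.05-fold higher in the labelled knockout), the RNA methyltransferase gene Nsun3 (at least 2.07-fold), the metal transporter gene Slc39a14 (1.42 ± 0.19) and St6gal2 (1.49 ± 0.21, or 0.36 with normexp). On the lower side stood Cidea (-1.61 ± 0.17), Lrrc15 (-1.43 ± 0.20), Zp3r, below background in both groups, and the epithelial ETS factor gene Elf3 (-1.48 ± 0.24, adjusted p 0.999), the last passing with limma over the ETS family list alone, as did the antiviral gene Oas1a (-0.90 ± 0.18) over the interferon list alone. Leaving out replicate 2 of the labelled knockout after OHT gave 386 calls and leaving out replicate 1 of it gave 129.

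Lists beyond those named so far did not pass camera on the group means. In the wild type after OHT 16 lists did not pass (adjusted p 0.206 to 0.982), in the labelled knockout 17 (0.227 to 0.763), for the difference 22 (0.255 to 0.945), between untreated genotypes 20 (0.0691 to 0.930) and between OHT-treated genotypes 20 (0.0598 to 0.927). Other fits passed some of them. The paired fit did so for fibroblast genes (adjusted p 3.42e-04, or 0.0276 on group means with dark patches out), cell cycle genes (0.0337) and interferon response genes (0.0384) for the difference. In the labelled knockout it did so for 2-cell-like (0.00747), cell cycle (0.0177), naive pluripotency (0.0205), trophoblast (0.0205) and cyclin-dependent kinase inhibitor genes (0.0208), and with an estimated correlation none of these passed (0.434 to 0.958). With the slide as a block, which sets pool B1 apart, 2-cell-like genes had 0.0213 between untreated genotypes and 0.00113 after OHT, where cholesterol synthesis genes had 0.0394. In all 5 comparisons the lists that did not pass on the group means included RAS-RAF-MEK-ERK pathway components, ETS family transcription factors, primitive streak and mesoderm, neuroectoderm, 2-cell-like, germline, cell cycle, cyclin-dependent kinase inhibitor, heat shock and stress response, interferon response, glycolysis and hypoxia, and estrogen receptor target genes. The median, mean and test of a list differed in sign for 0 lists in the wild type, 4 in the labelled knockout, 14 for the difference, 5 untreated and 6 after OHT, none of them among those that passed.

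Members of these lists with the smallest p in the wild type gave their own values, of which Etv1, the cell adhesion gene Ncam1 (1.94) and Oas1a (1.02) passed over their lists alone, as did Elf3 (1.67) and the RNA sensor gene Ddx58 (-1.05) besides. Outside those, the growth factor receptor gene Fgfr1 stood at 0.75, the naive gene Dppa3 at 0.96, the lipid carrier gene Apoe at 0.59, the organizer gene Gsc at 2.44 (1.12 with normexp), Eif1a at -0.25, the piRNA pathway gene Piwil2 at -1.27, the kinase gene Cdk6 at -1.66 and the cyclin-dependent kinase inhibitor gene Cdkn2d at 0.42. Sesn1 stood at 0.27, the fibroblast gene Fbln1 at 0.74, the stress gene Gadd45b at 1.16, the glucose transporter gene Slc2a3 at 0.78 and the lipase gene Lpl at 0.62. In the labelled knockout the corresponding values were 0.54 for Rras, -1.59 for Etv1, 2.03 for Tbx3, 1.06 for Ncam1, 0.45 for the placental hormone gene Prl3d1 (0.10 with normexp), 0.22 for Zfp352, -0.57 for Mov10l1 and -0.36 for the mitotic activator gene Cdc20. There Cdkn2a stood at 0.52, Ei24 at 0.36, Gadd45b at 0.86, Oas1a at 0.44, Slc2a3 at 0.61 and Lpl at 0.35, while Dab2 (-2.89, or -0.43 with dark patches left out) and Foxf1, below background after OHT, had spots in dark patches, so neither change is measured. With 1 array left out the wild type values ran from -2.57 to -0.76 for Cdk6, 0.35 to 1.13 for Fbln1 and 0.38 to 0.80 for Apoe, and normexp gave -0.39 for Cdk6, below background on 1 array. In the labelled knockout they ran from 0.23 to 0.85 for Rras, 0.59 to 1.52 for Ncam1, 0.14 to 0.30 for Zfp352, 0.16 to 0.57 for Ei24, 0.42 to 1.29 for Gadd45b, 0.41 to 0.82 for Slc2a3 and -5.39 to -0.39 for Dab2.

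**Figure D4:**
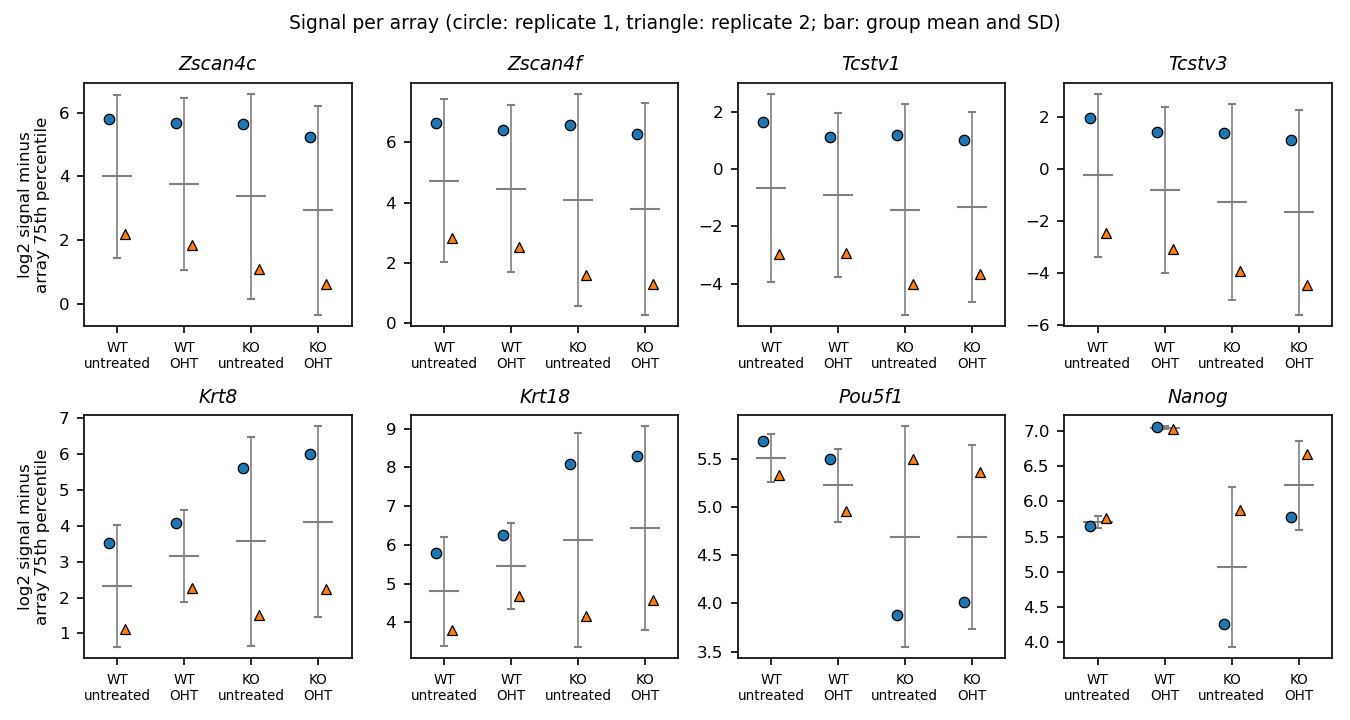
Log2 signal minus the array's 75th percentile (vertical axes) for 8 genes that set the cell pools apart, with one symbol per array and bars for the mean and SD of 2 arrays. Zscan4c, Zscan4f, Tcstv1 and Tcstv3 are higher in replicate 1 than in replicate 2 of every group, and Krt8 reaches 5.62 in untreated pool A2.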

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

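All the tests of explanations given here were chosen after the results were seen, while the list tests of the difference between genotypes were planned.

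RAS/ERK target genes stood out because the test of the difference between genotypes passed, at an adjusted p of 0.0347 by camera, or 0.968 with an estimated correlation: their fall after OHT was smaller in the labelled knockout. By pool, the median over members of the pair's change minus the wild type mean was 0.33 in A2, with 24 of 32 members higher. In B2 it was 0.0227, with 17 of 32 higher, so that A2 alone may carry it. The quartiles in B2, -0.16 and 0.60, include the value of A2. They give the scatter over genes, not the precision of the median, and so cannot decide this. Loss of ERF acting alike in both pools was thus not decided by the quartiles, and with 2 pools it cannot be told apart from a property of A2. Erf itself read low in A2 alone (3.45 and 3.92) and at the wild type level in B2 (5.65 and 5.31), so whether B2 lacks ERF stays unknown. Fibroblast genes moved with them in A2, by 0.54 with 19 of 20 members higher against 0.11 in B2, and the paired fit gave that list an adjusted p of 3.42e-04 for the difference, or 0.212 without A2 and 0.911 with an estimated correlation, so a change in the mix of cells in A2 stays open as well. How complete the loss of RAS was in each pool is a further candidate explanation and is not settled here.

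Trophoblast genes passed the same test at an adjusted p of 0.0347, or 0.968 with an estimated correlation, with a smaller rise in the labelled knockout. By pool, the median of the pair's change minus the wild type mean was -0.40 in A2 (15 of 19 lower) and -0.18 in B2 (13 of 20 lower), the same direction in both. The untreated cells already differed, with trophoblast genes higher and naive pluripotency genes lower in the labelled knockout (adjusted p 0.881 and 0.950 with an estimated correlation). A2 exceeded A1, which shares slide 1, by a lower quartile over trophoblast members of 0.34, so the slide does not account for that part. The quartile gives the scatter over genes of 1 array against 1, and naive pluripotency genes were not put to this test. For the difference between the groups the slide is not settled. With the slide as a block, camera gave adjusted p values of 0.139 for trophoblast and 0.158 for naive pluripotency genes. A state or mixture of cells particular to A2 could account for the untreated difference: the median trophoblast difference was 1.06 between A2 and A1 but 0.14 between B2 and B1, with naive pluripotency at -0.58 and 0.06. B2 and B1 lay on different slides, while within slide 1 A2 and B2 differed by 1.06 and -1.12. Clone history stays open and was not tested. An effect of losing ERF that shows in A2 alone stays open and was not tested.

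Genes called lower in the labelled knockout after OHT once its replicate 2 after OHT was left out, most of 384 calls, form another pattern. Dark patches on the remaining array are the likely source, since 90.1% of these genes had their spot in one, against 3.34% of all genes. A response to OHT is argued against, as the same genes had a median change of 0.0134 in the omitted pair, and 3 genes were called with the patches left out.

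Further genes had changes of one sign in both wild type pairs and of the other sign in both labelled knockout pairs. No single-gene difference among them passed the paired test, and some changes lay near 0. The difference of the effects was 1.35 for the piRNA pathway gene Piwil2 (adjusted p 0.0857). Piwil2 fell by 1.18 and 1.34 in the wild type pairs and stood at 0.02 and 0.15 in the labelled knockout pairs, so there the fall was absent. Prl3d1 differed by 0.68, the cell cycle inhibitor gene Cdkn2a by 0.67 and Ei24 by 0.44. Cdkn2a changed by -0.03 in pair B1, and Ei24 by -0.04 in A1 and 0.06 in A2. Pabpn1l (4.66), Gp1bb (3.47), Kctd7 (2.62) and Aldh3b2 (-3.31) were below background in 1 or 3 groups, and on the group means with a floor under dim probes they had 2.02, 0.99, 2.00 and -0.13, so their sizes are not measured. Pabpn1l and Gp1bb were below background in both wild type groups and Aldh3b2 in both labelled knockout groups, so their directions there are not measured either. The paired fit gave those last 7 genes adjusted p values from 0.245 to 0.741.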

How the results depend on the processing

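The pool-level blocks, the removal of dark patches and their combination were chosen after the data were seen, and the other settings were planned. Of the counts of called genes under alternatives 117 stayed at the reported value and 39 moved. Of the list results 333 kept their call, 163 kept their direction and lost it, and 6 turned. Settings that differ only in the trended and robust variance repeat the same list results in these counts. Among named genes 2776 values kept their sign and call, 153 gained one and 27 changed sign. Genes below background on both arrays of a group carry bounds where 2 groups are compared, which hold for this scaling and are larger than most changes of these genes with normexp and its offset of 50, and for the difference a floor under dim probes gave 2.02 for Pabpn1l, 0.99 for Gp1bb, 1.74 for Slc16a12, 2.00 for Kctd7, -0.48 for Slfn1 and -0.13 for Aldh3b2. The values of the deposited series table were not run as an alternative, because its probe names were not borne out, and normexp used the median spot signal. With median centring the median over all genes was 0.16 in the wild type, -0.18 in the labelled knockout, -0.35 for the difference, 0.25 untreated and -0.10 after OHT, against -0.05, 0.02, 0.05, -0.02 and 0.03 with the 75th percentile, and changes are best read relative to these.

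Counts in the wild type after OHT, 0 as reported, became 5 (2 higher, 3 lower) with normexp, 4 (1 and 3) over probes well above background on all arrays, 3 (0 and 3) with a trended and robust variance, 14 (5 and 9) with array weights and 4 (1 and 3) at an adjusted p under 0.1. With dark patches out and the replicate block the count was 28 (9 and 19), with the pool block and a trended and robust variance 1458 (626 and 832), and with the pool block and dark patches out 267 (129 and 138). The paired fit gave 2686 (1183 and 1503), or 575, 3164, 465 and 3144 without pools A1, A2, B1 and B2, and 2757 with a patch limit of -0.5. In the labelled knockout the pool block with a trended and robust variance gave 383 (206 and 177) and the paired fit 2149 (694 and 1455), or 1060, 667, 1087 and 903 without A1, A2, B1 and B2, and 2245 with the patch limit of -0.5. For the difference the paired fit gave 3, 10, 10 and 65 without those pools. Pools as blocks lowered the median residual SD from 0.305 to 0.111 and alone called 0 genes, and the cause was not tested for the other settings. The replicate block alone called 0 genes in each comparison.

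Leaving out 1 array at a time gave counts from 0 to 29 in the wild type (29 without untreated replicate 2), 0 to 384 in the labelled knockout and 0 to 325 for the difference (the highest without replicate 2 of the labelled knockout after OHT in both), 0 to 21 untreated and 0 to 386 after OHT. Where a group kept 1 array, that array was assumed to vary like the other groups. Such a fit on the group means compares unequal sets of pools, so level differences between pools enter it. Adjusted p for RAS/ERK targets ran from 3.10e-10 to 0.273 in the labelled knockout and from 2.75e-04 to 0.801 for the difference, where the direction turned without replicate 1 after OHT. Fibroblast genes ran from 1.07e-05 to 0.762 in the labelled knockout and from 1.21e-04 to 0.542 between genotypes after OHT, turned without the same array. Trophoblast genes ran from 3.09e-06 to 0.990 for the difference and from 1.23e-05 to 0.897 untreated, and naive pluripotency genes from 4.91e-06 to 0.463 untreated, all 3 turned without replicate 1 of the untreated labelled knockout. How far level differences between pools account for these ranges was not tested.

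An estimated correlation ended all 25 list calls and so did fry, with the cause not tested. For RAS/ERK targets the adjusted p was 0.574 and 0.111 by fry in the wild type, 0.511 and 0.436 in the labelled knockout, and 0.968 and 0.991 for the difference. In the paired fit an estimated correlation gave 0.532, 0.434 and 0.911 in that order, and fry kept the wild type call, with 0.05003 in the labelled knockout and 0.523 for the difference. The difference had 0.0983 with the slide as a block and 0.0913 with the pool-level replicate block. The trended and robust variance does not enter the list tests, so it could not change these values. Calls ended for 9 of 25 lists with the slide block, 4 with the replicate block (0.0627, 0.0627 and 0.0883 for DNA methylation, cholesterol synthesis and TGF-beta, BMP and Nodal genes in the wild type and 0.101 for naive pluripotency after OHT), 6 with quantile normalisation, 4 with normexp, 2 with dark patches out, and 2 of 17 in the paired fit. The pool-level replicate block ended 5 of 17, the 4 narrow wild type lists and the RAS/ERK difference, and no other list call.

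Among the targeted genes, Erf in the labelled knockout turned to -0.13 with median centring and to -0.0015 with dark patches out, whether alone, with the replicate block, with the pool block or in the paired fit. Its difference turned to -0.013 with median centring. Median centring turned the differences of Hras and Nras to -0.24 and -0.16 and Hras untreated to 0.10, while Hras after OHT turned to 0.0063 with quantile normalisation and 0.0566 with normexp. A floor turned Zp3r to 0.0807 for the difference and 0.12 after OHT, and Ptprd untreated to -0.0305, as dim values sit at the floor.

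With 1 array left out Nras ran from -0.23 to 0.64 in the wild type and from -0.19 to 0.68 for the difference. Erf ran from -1.03 to 1.16 in the labelled knockout, from -0.71 to 1.49 for the difference, from -1.82 to 0.37 untreated and from -1.03 to 0.36 after OHT. Hras ran from -0.27 to 0.012 in the labelled knockout and from -0.097 to 0.096 after OHT. For Erf the unequal sets of pools account for these ranges. Pool A2 read 3.45 untreated and 3.92 after OHT, while pool B2 read 5.65 and 5.31. Leaving out 1 of these arrays lets that gap between pools enter the values. The same holds for Nras in the wild type, where A1 read 0.87 untreated and 0.99 after OHT and B1 read 1.58 and 1.87. Hras in the labelled knockout read 2.86 and 2.78 in A2 and 3.15 and 2.97 in B2, a smaller gap that enters alike. Whether the Hras gap lies in the pools or in single arrays was not tested.

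The median change kept moved in 7 cases. Without a filter on dim probes it was 0.333 in the wild type and 0.0812 in the labelled knockout for genes chosen on pair 1, and 0.661 and 0.273 on pair 2. With a difference of at least 1.5 required it was 1.12 in the wild type on pair 1, and 1.33 and 0.848 on pair 2. The correlation across genes was 0.395 with normexp, 0.194 without a filter and 0.551 with dark patches out, and ran from 0.201 without replicate 2 to 0.288 without replicate 1.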

Other observations

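The tests of this part, a contrast of the A pools with the B pools on the means of the 4 pools, with dark patches left out and a trended and robust variance, and its list tests, were chosen after the results were seen. With 2 pools a side, this fit has 1 residual degree of freedom, so its SEs lean on the spread of other genes. Of the 4 pools B1 alone lay on slide 2, so A1 against B1, and with it the contrast, mixes pool and slide. A2 and B2 share slide 1. The cell pools differed most in 2-cell-like genes, which mark a rare state resembling the early embryo. Over 16 measured members the median was 4.20 higher in the A pools than in the B pools, and 13 members were called. Within slide 1 the median between A2 and B2 was 4.57 untreated and 4.72 after OHT. Zscan4c and Zscan4f, telomere-associated genes of that state, were 4.14 ± 0.23 and 4.39 ± 0.28 higher (limma SE over 4 pools, adjusted p 6.22e-05 and 0.00161), and Tcstv1 was 4.64 ± 0.30 higher (adjusted p 1.35e-05). Trophoblast genes were higher in the A pools too, by a median of 0.74 with 5 called, and p53 targets by 0.46 with 2 called. Between A2 and B2 their medians were 1.06 and 0.63 untreated and 1.09 and 0.95 after OHT, and between A1 and B1 they were 0.14 and 0.18 untreated and 0.33 and 0.34 after OHT. The keratin genes Krt8 and Krt18 of early epithelia stood at 3.01 ± 0.54 and 2.78 ± 0.65 (adjusted p 0.100 and 0.178). By camera the lists had adjusted p values of 4.29e-19 for 2-cell-like, 0.00379 for trophoblast and 6.73e-04 for p53, or 0.913, 0.940 and 0.940 with an estimated correlation. Camera also passed formative and primed epiblast (5.78e-04), primitive streak and mesoderm (0.00403), WNT response (0.00403), TGF-beta, BMP and Nodal response (0.0181), fibroblast (0.0256), RAS/ERK target (0.0357) and neuroectoderm genes (0.0445) as higher in the A pools and naive pluripotency (0.0182) and cell cycle genes (0.0279) as lower, with adjusted p values of 0.913 to 0.945 with an estimated correlation. Not all of these lists went the same way in both genotypes. Between A1 and B1 fibroblast genes had medians of -0.25 untreated and -0.56 after OHT, against 0.82 and 1.06 between A2 and B2. RAS/ERK targets had -0.07 and 0.04 between A1 and B1, against 0.18 and 0.23 between A2 and B2. In all, 757 of 14227 genes were called, 283 higher in the A pools and 474 lower, against 86 with a plain eBayes, 70 higher and 16 lower.

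Between pools of the same letter other gene groups set the genotypes apart by unequal amounts, and fibroblast genes in opposite directions, described without a test. Pool B1 alone lay on slide 2, so each value of B2 against B1 mixes pool and slide, while A2 and A1 share slide 1. Among untreated pools, fibroblast genes were 0.60 higher in A2 than in A1 but -0.40 in B2 against B1, and after OHT the medians were 1.29 and -0.30. Primitive endoderm genes were at -0.79 in B2 against B1 and at -0.06 in A2 against A1. Target genes of p53 were at 0.58 in A2 against A1 and at 0.08 in B2 against B1. The pluripotency regulator Pou5f1 read 3.88 and 4.02 in pool A2 without and with OHT, below its values of 4.96 to 5.68 in the other pools, while Krt8 read 5.62 there untreated.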
